A study of Mus musculus with 6 samples.

How the data were processed

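RNA was measured in primary brain microvascular endothelial cells of C57BL/6 mice, the cells that line brain capillaries and form the blood-brain barrier. Confluent cultures received either the vehicle dimethyl sulfoxide (DMSO, 3 libraries) or dolutegravir (DTG, an HIV integrase inhibitor) at 5000 ng/ml for 24 h (3 libraries). Per the labels' protocols, cells between passages 2 and 6 were grown in medium with 5% serum, RNA was isolated with TRIzol, and 2 µg per library entered a strand-preserving poly(A) kit (TruSeq Stranded mRNA). Library names also carry a P4 or P5 tag, which the labels do not define; 1 DMSO and 2 DTG libraries carry P4, and 2 DMSO and 1 DTG library carry P5. The column of DTG replicate 1 is spelled DIG and was matched to its sample by the remaining parts of its name. Library names also hold a number that differs in part from the title number. It is 1, 1 and 3 for DMSO replicates 1, 2 and 3, and 2, 2 and 3 for DTG replicates 1, 2 and 3. What this number stands for is not stated, and it was not used as a block. Libraries of a group that share it may not be independent. The labels do not say whether libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

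The authors deposited 1 table of raw counts per Ensembl gene identifier, with whole numbers and no normalization, for 43271 genes. Per the submitters' processing notes the genome build was GRCm39. The aligner, the counting tool, its strand setting and the annotation version are not given in the sources used here. Gene names came from a reference table that matched 38606 identifiers (89.2%); identifiers without a match held between 0.33% and 0.49% of the counts of a library. The reference genome at hand was of another build, so no coordinates are given, and transcript length, GC content and neighbouring genes were taken from it by gene identifier. Total counts ranged from 41162353 to 56316335 per library, which leaves counting error small except for genes with a few counts. Intervals and floors cover counting error only.

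Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group as factor (14101 genes), libraries were scaled by TMM, and DTG was compared with DMSO by edgeR's quasi-likelihood F-test with robust dispersion estimation and group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05, and every adjusted p of a single gene comes from this test unless another is named. Standard errors are the absolute log2 fold change divided by the square root of F. Expression is given as CPM (counts relative to the TMM-scaled library size), as mean ± SD over the 3 libraries of a group.

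Gene lists were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Camera compares a list with all other genes, whereas fry asks whether the genes of a list move on balance one way and does not compare them with other genes. The 30 pathway lists form 1 family for adjustment and 9 lists of markers of other cell types a second family. Of 780 list entries 779 matched a gene, 19 of them through an older symbol. The design, these lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 genes with the largest change in each direction among those that passed, that were separated between groups and that reached at least 5 CPM in the higher group (leaving out predicted genes named Gm, Rik or -ps), the 4 smallest p-values of each list that passed, the 2 smallest of each other list, and 15 fixed genes. Genes named outside it, as members of a list, were chosen after their values were seen. Some members of the lists are not reported here by name.

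Alternatives were DESeq2 1.42.0, limma-voom, RLE, upper-quartile and library-size scaling, other count filters, no robust estimation, a stricter threshold, a fold threshold, a replicate block, the P tag as a term, and leaving out each library in turn. Of these, 11 were run on each named gene (DESeq2, RLE, library size, block, tag and the 6 libraries) and 11 on each camera result (a 1 CPM filter in place of DESeq2). A treatment by tag interaction and the differences within each tag were added after seeing the data, as were 9 further gene lists. The pipeline was tested on simulated counts for the comparison of DTG with DMSO, in 3 runs with 13913 genes tested in the first. At log2 changes of 0.25, 0.5, 1 and 2 it recovered 3.4%, 46.6%, 84.4% and 95.9% of the changed genes, and 8.9% of its calls were false. Each run changed 200 genes, far fewer than passed in the data, so these shares need not hold for the real comparison. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Genes that share reads with near-identical copies (Hspa1a and Hspa1b, the Ifit, Ifi27l2, Ms4a and Ly6 families, Ugt1a, and ribosomal protein genes, Gapdh and Eno1 with their pseudogenes) and overlapping or antisense genes are uncertain, since the counting of such reads is not stated.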

Results

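The series measured how dolutegravir changes gene expression in cultured mouse brain endothelial cells, and its title places the question in endoplasmic reticulum (ER) stress and the blood-brain barrier. The 3 DMSO libraries held 47574809, 55998253 and 41162353 counts and the 3 DTG libraries 56316335, 54728627 and 51344169. The first principal component (80.2% of variance) separated the groups, with DTG replicate 1 at 39.7 and DTG replicates 2 and 3 at 55.0 and 53.6. On the second (8%) the P4 libraries lay between 7.04 and 18.8 and the P5 libraries between -24.1 and 2.05. Across genes, which are not independent replicates, log2 CPM correlated at 0.991 to 0.995 within groups and at 0.953 to 0.965 between groups. The 10 most abundant genes took 5.01% ± 0.27 of the counts in DMSO and 7.06% ± 0.10 in DTG (SD, n = 3 each, two-sided exact permutation p = 0.1, the smallest that 3 against 3 allow). The mitochondrial share was 2.47%, 3.09% and 4.27% in the DMSO libraries and 3.58%, 2.75% and 2.80% in the DTG libraries, lower in each P4 than in each P5 library.

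**Figure D1:**
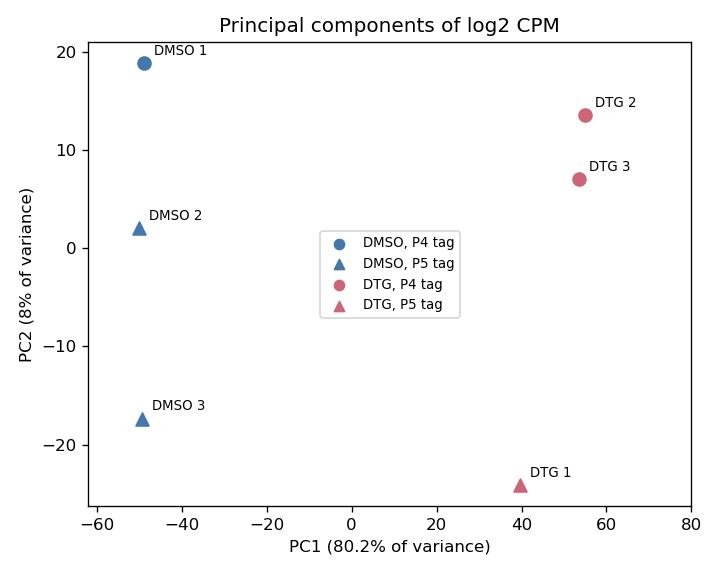
Principal components of log2 CPM over the 6 libraries, with PC1 on the horizontal and PC2 on the vertical axis, colour for the treatment and symbol for the P tag. DMSO libraries lie between -50.1 and -48.95 on PC1 and DTG libraries between 39.7 and 55.0.

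DTG cultures showed a large rise of ER chaperones and of amino acid stress genes, together with lower levels of many endothelial, interferon and mitotic genes. Hspa5, the ER chaperone BiP, rose from 720.2 ± 40.4 to 13380 ± 2353 CPM (SD, n = 3 each), a log2 change of 4.22 ± 0.14 (SE, adjusted p = 2.92e-08), with 4.45 within the P4 and 3.84 within the P5 libraries. Ddit3, which encodes the stress transcription factor CHOP, rose from 19.4 ± 2.34 to 586 ± 160 CPM. The claudin gene Cldn5, the main endothelial tight junction strand protein, fell from 875 ± 117 to 548 ± 63.2 CPM. The von Willebrand factor gene Vwf fell from 2958 ± 422 to 950 ± 37.7 CPM.

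Of 14101 genes tested, 3860 were higher and 4130 lower in DTG, together 56.7%. A log2 change of at least 1 was reached by 885 of the higher and 1177 of the lower genes. In 64.2% of all genes the groups did not overlap, where chance gives 10%. Of the 7990 genes that passed, 7986 (99.9%) had the same sign in the P4 and in the P5 libraries taken alone, as did 85.3% of all genes tested, the former having been selected on these libraries, and the P4 and P5 differences correlated at 0.886 across all genes tested. Relative to TMM, scaling by library size alone shifted the median of all genes by -0.17 log2, so changes are given relative to TMM. The share of calls that were higher was 48.3% with TMM, 30.7% with library size alone and 38.2% with upper-quartile factors.

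Most of the 10 largest increases were in genes near the detection limit in DMSO. Mamdc2 had 1 count in the DMSO libraries together and 1589 in the DTG libraries, a ratio of 1594 (95% exact counting interval 286 to 63000). Otog had 3 and 1527 counts, a ratio of 511 (174 to 2479). Cox6a2, Gsdma, Csn3 and Tenm4 each rose from at most 0.2 CPM to between 7.24 and 20.2 CPM. Acox2, a peroxisomal oxidase of branched-chain lipids, rose from 0.406 ± 0.127 to 60.2 ± 14.3 CPM. Il12b and Il23a, whose products pair to form interleukin 23, rose by 6.91 ± 0.54 and 6.89 ± 0.38 log2 (adjusted p = 5.13e-05 and 3.99e-06) and reached 21.5 ± 9.28 and 35.0 ± 12.1 CPM. Aldh1l2, the mitochondrial formyltetrahydrofolate dehydrogenase, had the smallest p of the 10, rising from 3.83 ± 0.23 to 415 ± 36.1 CPM (adjusted p = 3.06e-10). Among the 10 largest decreases, the apelin receptor gene Aplnr fell by 4.61 ± 0.43 log2 and the growth factor gene Igf1 from 164 ± 43.4 to 10.4 ± 3.51 CPM. The sulfotransferase gene Sult1a1 fell from 39.3 ± 3.17 to 2.82 ± 0.09 CPM. Rgcc, Duox2, Itga8, Tnfsf10 and Nepn fell by between 3.28 and 4.16 log2, and Ms4a6b and Ifi27l2b, which have close paralogs, by 3.69 and 3.67.

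Genes of the ATF6 and XBP1 arms of the unfolded protein response, which raise folding and disposal capacity in the ER, rose without exception: 28 of 28 measured members passed as higher (28 adjusted over the list alone), with a median of 2.78 log2. The median was 2.81 within the P4 and 2.50 within the P5 libraries. Creld2 rose 46.1-fold to 1995 ± 431 CPM and Pdia4 27.9-fold to 4651 ± 483 CPM. Hsp90b1, the ER paralog of HSP90, rose from 1100 ± 77.5 to 16580 ± 1110 CPM and became the most abundant transcript of each DTG library, where mt-Co1 led in each DMSO library. Xbp1 itself rose 2.53-fold and Sdf2l1 23.4-fold. The list stood apart from other genes (camera adjusted p = 3.09e-90), with adjusted p = 0.136 with an estimated correlation.

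In the PERK, ATF4 and CHOP arm, 20 of 23 measured members rose and 1 fell (20 and 2 adjusted over the list alone), with a median of 2.25 log2, 2.38 within P4 and 1.79 within P5. Atf4 rose 5.45-fold, Trib3 9.78-fold, Nupr1 14-fold and the ER oxidase gene Ero1l 9.55-fold. Chac1, a glutathione-degrading enzyme gene, rose from 5.16 ± 0.25 to 114 ± 42.7 CPM. The lipoprotein receptor gene Vldlr fell by 1.22 ± 0.11 log2, and Bbc3 and Ddit4 differed by -0.34 and -0.12 log2 and did not pass, Bbc3 being the added lower gene over the list alone. Camera gave adjusted p = 1.10e-15 for this list, and adjusted p = 0.196 with an estimated correlation. Amino acid synthesis and transport genes and the transfer RNA synthetases rose in 26 of 26 cases (26 adjusted over the list alone). Their median was 2.05 within P4 and 1.46 within P5 libraries (1.90 over all). Pycr1, which makes proline, rose 15.4-fold, the serine synthesis gene Phgdh 5.02-fold and the tryptophan synthetase gene Wars 4.42-fold (camera adjusted p = 1.75e-24, and adjusted p = 0.196 with an estimated correlation).

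**Figure D2:**
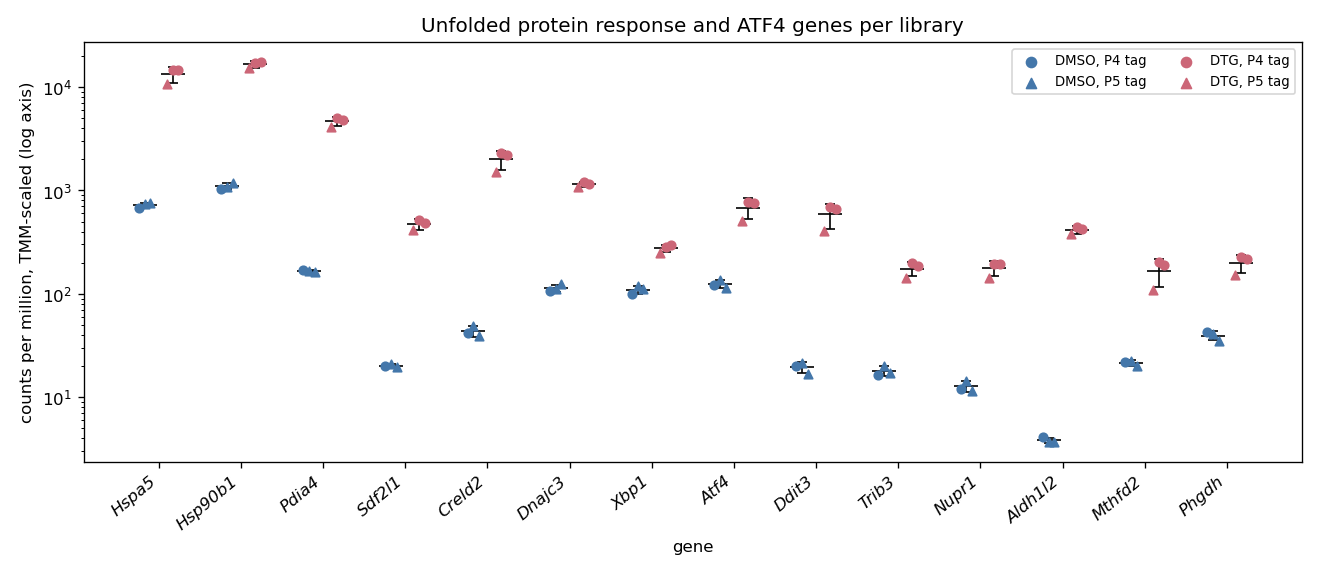
TMM-scaled CPM on a log axis for unfolded protein response and ATF4-linked genes, 1 point per library (blue DMSO, red DTG, circles P4, triangles P5), with group mean and SD in black. Each of the 14 genes lies higher in every DTG than in every DMSO library, from 2.53-fold (Xbp1) to 108.3-fold (Aldh1l2).

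Cytosolic chaperones moved less. Of 15 measured heat shock genes 8 rose and 1, Hspa4l, fell (8 and 1 adjusted over the list alone), with a median of 0.26 log2, but 3 rose and 4 fell with library-size scaling, with a median of 0.09. Hsph1 rose 2.58-fold, the mitochondrial chaperone genes Hspd1 and Hspe1 rose 2.08-fold and 1.85-fold, and Hspa1a and Hspa1b, near-identical copies, differed by -0.23 and 0.07 log2 without passing. The list had camera adjusted p = 0.0417, and adjusted p = 0.196 with an estimated correlation. Its call was lost in 5 of 11 alternatives, namely library-size scaling, a filter at 1 CPM, the P tag as a term, and without DMSO replicate 1 (adjusted p = 0.0599) or DTG replicate 1 (0.0915), with a range from 0.028 to 0.0915.

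Tight junction genes were lower in part. Of 17 measured members 9 fell and 1 rose (9 and 1 adjusted over the list alone), with a median of -0.27 log2, -0.22 within P4 and -0.20 within P5. With library-size scaling 12 fell and 0 rose, with a median of -0.43. Cldn5 fell by 0.67 log2 (SE 0.12, adjusted p = 0.000696), with -0.88 within P4 and -0.43 within P5. The junctional adhesion genes Jam2 and Jam3 fell by 0.94 and 1.39 log2, and Cldn12 rose by 0.39. Tjp1, which encodes the scaffold ZO-1, fell by 0.22 ± 0.08 log2 (adjusted p = 0.0447), and this call was lost in 7 of 11 alternatives, among them without DMSO replicate 1 or 3 (adjusted p = 0.0719 and 0.0875) and without DTG replicate 2 or 3 (0.239 and 0.212), with a range from 0.00274 to 0.239. Ocln, the occludin gene, differed by -0.19 ± 0.08 log2 and did not pass (adjusted p = 0.0639), though it did with library-size scaling (adjusted p = 0.0035, range over alternatives 0.0035 to 0.262). As a list the tight junction genes missed the camera threshold (adjusted p = 0.072) and passed fry (adjusted p = 0.000284).

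Of 20 adherens junction and focal adhesion genes 5 rose and 8 fell (5 and 8 adjusted over the list alone, camera adjusted p = 0.405), while 1 rose and 10 fell with library-size scaling and 3 rose and 10 fell with upper-quartile factors. Cdh5, the endothelial cadherin gene, was at 1874 ± 117 CPM in DMSO and 2115 ± 106 in DTG and did not pass (0.17 ± 0.08 log2, adjusted p = 0.0994). It passed as higher with DESeq2 and without DTG replicate 1 (adjusted p = 0.0447 and 0.0228, range over alternatives 0.0228 to 0.982). Ptprb, a phosphatase that acts on VE-cadherin, fell 2.54-fold and the collagen receptor gene Itga1 2.15-fold.

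**Figure D3:**
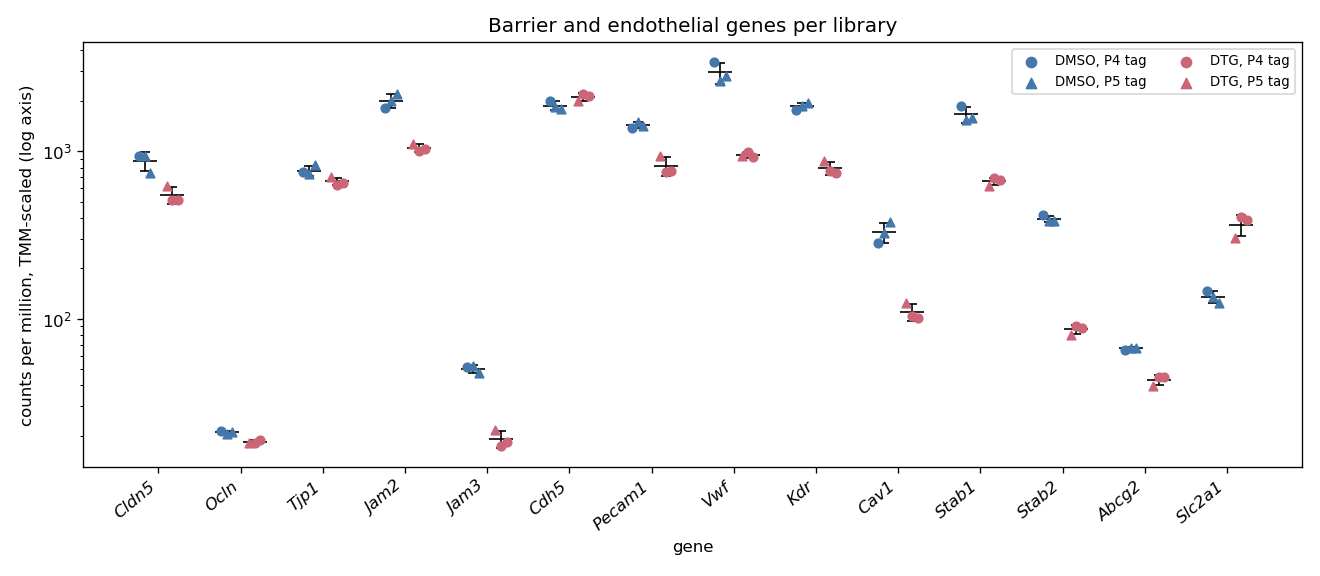
TMM-scaled CPM on a log axis for barrier and endothelial genes, 1 point per library (blue DMSO, red DTG, circles P4, triangles P5), with group mean and SD in black. Vwf, Kdr, Stab2 and Jam3 lie lower in every DTG library than in every DMSO library. Ocln does so by a small difference (21.0 against 18.3 CPM), while Cdh5 (1874 against 2115 CPM) overlaps between the groups.

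Genes of endothelial identity fell in 21 of 30 cases and rose in 2 (21 and 2 adjusted over the list alone), with a median of -0.64 log2, -0.61 within P4 and -0.52 within P5. Kdr, the main VEGF receptor gene, fell 2.33-fold, Clec14a 2.97-fold and Pecam1 1.75-fold. The transcription factor genes Sox17, Sox18, Erg and Fli1 fell by between 0.55 and 0.93 log2. Nos3 and Robo4 were the 2 that rose, by 0.42 and 0.61 log2. Camera gave adjusted p = 1.65e-06, and adjusted p = 0.196 with an estimated correlation. Genes of caveolae and vesicular transport fell in 8 of 13 cases and rose in 3 (8 and 3 adjusted over the list alone), with a median of -0.77 log2. Cav1, the caveolin gene, fell 3.01-fold and Cavin2 2.43-fold, and the scavenger receptor genes Stab1 and Stab2 fell 2.52-fold and 4.56-fold, whereas Pacsin2 rose 2.40-fold. The camera adjusted p was 5.95e-05, with adjusted p = 0.160 with an estimated correlation.

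Blood-brain barrier transporter and efflux genes moved in both directions, with 11 of 19 higher and 5 lower (11 and 5 adjusted over the list alone, camera adjusted p = 0.235). The list passed only without DTG replicate 1 among its 11 alternatives of scaling, filter, covariate and library (adjusted p = 0.0057, range 0.0057 to 0.378). The glucose transporter gene Slc2a1 rose 2.70-fold to 365 ± 53.5 CPM and the amino acid transporter gene Slc7a5 6.84-fold. Slc7a5 and Slc3a2 are also members of the PERK, ATF4 and CHOP list, and Slc7a1 of the amino acid list. The efflux pump gene Abcg2 fell from 66.6 ± 0.91 to 43.3 ± 2.98 CPM, the nucleoside transporter gene Slc29a1 fell 4.05-fold and Slc16a4 4.47-fold. Of the P-glycoprotein genes, Abcb1a was at 0.833 ± 0.009 and 0.882 ± 0.172 CPM (adjusted p = 0.782) and Abcb1b at 47.1 ± 0.67 and 40.5 ± 5.44 CPM (adjusted p = 0.0882). Wnt targets and maturation genes of the barrier fell in 7 of 13 cases and rose in 0 (7 and 0 adjusted over the list alone), with a median of -0.45 log2 that was -0.19 once the trend over transcript length and GC content was removed. Apcdd1 fell 1.64-fold and Lrp5 1.59-fold, while Spock2 and Itm2a fell from 1.89 to 0.530 CPM and from 2.21 to 0.712 CPM. The camera adjusted p was 0.0392, with adjusted p = 0.237 with an estimated correlation, and it was 0.0561 and 0.0508 without DTG replicate 1 and 3 (range over alternatives 0.028 to 0.0561).

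Folate and one-carbon genes rose in 10 of 18 cases and fell in 2 (10 and 2 adjusted over the list alone), with a median of 0.32 log2. With library-size scaling 7 rose and 2 fell, with a median of 0.15. The members that rose most belong to the mitochondrial branch: Aldh1l2, Mthfd2 (7.81-fold) and Shmt2 (4.11-fold). Mthfd2 and Shmt2 are also members of the amino acid list above, so these lists are not independent. The reduced folate carrier gene Slc19a1 was at 16.2 ± 0.91 and 16.7 ± 0.68 CPM (adjusted p = 0.749). Slc46a1, with 33 counts in DMSO and 18 in DTG, and Folr1, with 4 and 0, were too low to be tested. The camera adjusted p was 2.71e-06, and adjusted p = 0.196 with an estimated correlation. Metal handling genes rose in 9 of 15 cases and fell in 2, or 6 and 4 with library-size scaling (9 and 2 adjusted over the list alone with TMM), led by the metallothioneins Mt2 and Mt1, at 0.483 and 0.835 CPM in DMSO and 25.2 ± 7.40 and 10.2 ± 1.20 CPM in DTG. The magnesium transport gene Magt1, also a subunit of the oligosaccharyltransferase, rose 2.84-fold (list adjusted p = 0.000766 by camera, and adjusted p = 0.184 with an estimated correlation).

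Cholesterol synthesis genes rose in 17 of 23 cases and fell in 1 (17 and 1 adjusted over the list alone), with a median of 0.73 log2, 0.78 within P4 and 0.77 within P5. Fdps rose 4.00-fold, Msmo1 3.15-fold, Fdft1 2.74-fold and Sqle 2.47-fold (camera adjusted p = 1.02e-10, and adjusted p = 0.196 with an estimated correlation). Glycolysis and hypoxia genes rose in 17 of 24 cases and fell in 2 (17 and 2 adjusted over the list alone), with a median of 0.54 log2. Hk2 rose 5.91-fold, Vegfa 3.55-fold and Pgk1 2.17-fold (camera adjusted p = 7.59e-06, and adjusted p = 0.196 with an estimated correlation).

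NF-kB, cytokine and adhesion genes split into members with large increases and members without. Il6 rose from 2.99 ± 0.92 to 210.8 ± 7.01 CPM, and the neutrophil chemokine genes Cxcl1 and Cxcl2 rose 4.65-fold and 21.2-fold. Csf3 rose 4.95-fold and the P-selectin gene Selp 2.04-fold, whereas Tnfaip3, Cx3cl1, Cxcl12 and Csf1 fell. Of 24 measured members 11 rose and 4 fell (11 and 4 adjusted over the list alone), with a mean of 0.69 and a median of 0.10 log2 (0.22 within P4 and 0.21 within P5) that was -0.07 with library-size scaling. The camera adjusted p was 0.000766, and adjusted p = 0.196 with an estimated correlation. Interferon response genes fell in 21 of 25 cases and rose in 1 (21 and 1 adjusted over the list alone), with a median of -0.88 log2, -0.81 within P4 and -0.82 within P5. Gbp2 fell 3.38-fold, Oas2 3.51-fold and Oasl2 3.21-fold, and Isg20 was the 1 that rose, 3.37-fold (camera adjusted p = 1.83e-06, and adjusted p = 0.383 with an estimated correlation).

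Proliferation genes were lower in these confluent cultures. All 25 measured mitotic (G2 and M phase) genes fell (25 adjusted over the list alone), with a median of -1 log2, -0.92 within P4 and -1.09 within P5. Mki67 fell 2.30-fold, Cenpa 2.2-fold and Kif20a 2.10-fold (camera adjusted p = 3.01e-16, and adjusted p = 0.196 with an estimated correlation). Of 25 S phase genes 19 fell and 1 rose (19 and 1 adjusted over the list alone), with a median of -0.49 log2. Rrm1 and Rrm2, subunits of ribonucleotide reductase, fell 1.74-fold and 1.55-fold, and the uracil glycosylase gene Ung rose 2.25-fold (camera adjusted p = 0.00194, and adjusted p = 0.545 with an estimated correlation).

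Basement membrane and matrix genes fell in 14 of 20 cases and rose in 1 (14 and 1 adjusted over the list alone), with a median of -0.52 log2. Col4a1 fell from 3370 ± 405 to 1701 ± 115 CPM, Agrn 2.75-fold, Lamb2 2.29-fold and Lama4 1.85-fold (camera adjusted p = 0.000264, and adjusted p = 0.316 with an estimated correlation). Matrix proteases and their inhibitors rose in 5 and fell in 5 of 15 cases, or in 4 and 8 with library-size scaling (5 and 6 adjusted over the list alone, camera adjusted p = 0.793). Among the inhibitors Timp2 fell 2.55-fold and Timp3 fell from 1225 ± 139 to 345 ± 92.1 CPM, while Timp1 rose from 15.2 ± 1.77 to 36.7 ± 0.81 CPM.

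The remaining lists missed the camera threshold. NRF2 targets rose in 10 and fell in 2 of 21 cases, or in 5 and 3 with library-size scaling (10 and 2 adjusted over the list alone, adjusted p = 0.081), with Slc7a11 up 3.14-fold, Hmox1 up 2.84-fold and Nqo1 down 1.45-fold. This list passed without DMSO replicate 1, DMSO replicate 2 or DTG replicate 2 (adjusted p = 0.0413, 0.0375 and 0.0431, range over alternatives 0.0375 to 0.280). Angiogenesis and Notch genes rose in 4 and fell in 12 of 24 cases (4 and 13 adjusted over the list alone, adjusted p = 0.0588) and passed without any 1 of the DMSO replicates (range over alternatives 0.0309 to 0.174). Flow-responsive and vasodilator genes rose in 4 and fell in 7 of 16 cases (6 and 7 adjusted over the list alone, adjusted p = 0.277), with Ace and Ptgs1 down 1.84-fold and 1.95-fold. Endothelial-to-mesenchymal transition genes rose in 3 and fell in 8 of 21 cases (3 and 8 adjusted over the list alone, adjusted p = 0.509), in which Acvrl1 and Vim fell by 0.73 log2 each. Xenobiotic response genes rose in 2 and fell in 4 of 13 cases (2 and 4 adjusted over the list alone, adjusted p = 0.574), with a median of -0.12 log2 that was -0.28 within P4, 0.08 within P5 and -0.29 with library-size scaling, and the receptor gene Ahr fell 2.07-fold. Fatty acid genes rose in 6 and fell in 7 of 19 cases, or in 3 and 9 with library-size scaling (6 and 7 adjusted over the list alone, adjusted p = 0.547), with Fabp5 down 3.30-fold. For p53 targets 8 rose and 8 fell of 23, or 6 and 11 with library-size scaling (8 and 9 adjusted over the list alone, adjusted p = 0.762), and Sesn1 fell 3.80-fold. Lysosome and autophagy genes rose in 7 and fell in 9 of 25 cases (7 and 9 adjusted over the list alone), with a median of 0.07, a mean of -0.01 a downward camera test (adjusted p = 0.9996) and a median of -0.10 with library-size scaling. Lamp1 fell 1.75-fold and Sqstm1, the p62 gene, rose 1.95-fold. Nuclear genes of oxidative phosphorylation rose in 6 and fell in 3 of 30 cases (4 and 1 adjusted over the list alone, adjusted p = 0.538), with a median of 0.07 log2. With library-size scaling 3 rose and 9 fell, with a median of -0.11. Atp5g1 and Uqcrq rose by 1.30 and 0.84 log2. Mitochondrially encoded genes rose in 2 and fell in 1 of 13 cases, or 1 and 2 with library-size scaling (1 and 1 adjusted over the list alone, adjusted p = 0.543), and this list passed as higher only without DMSO replicate 3 among its 11 alternatives (adjusted p = 0.0179, range 0.0179 to 0.942). Of its members mt-Co1 fell by 0.53 log2, a call lost without DMSO replicate 3 or DTG replicate 2 or 3 (adjusted p = 0.0507, 0.0542 and 0.0539, range 0.000763 to 0.0542), and mt-Nd2 rose by 0.78 log2, a call lost without DMSO replicate 2 (adjusted p = 0.0524, range 8.41e-05 to 0.0524).

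**Figure D4:**
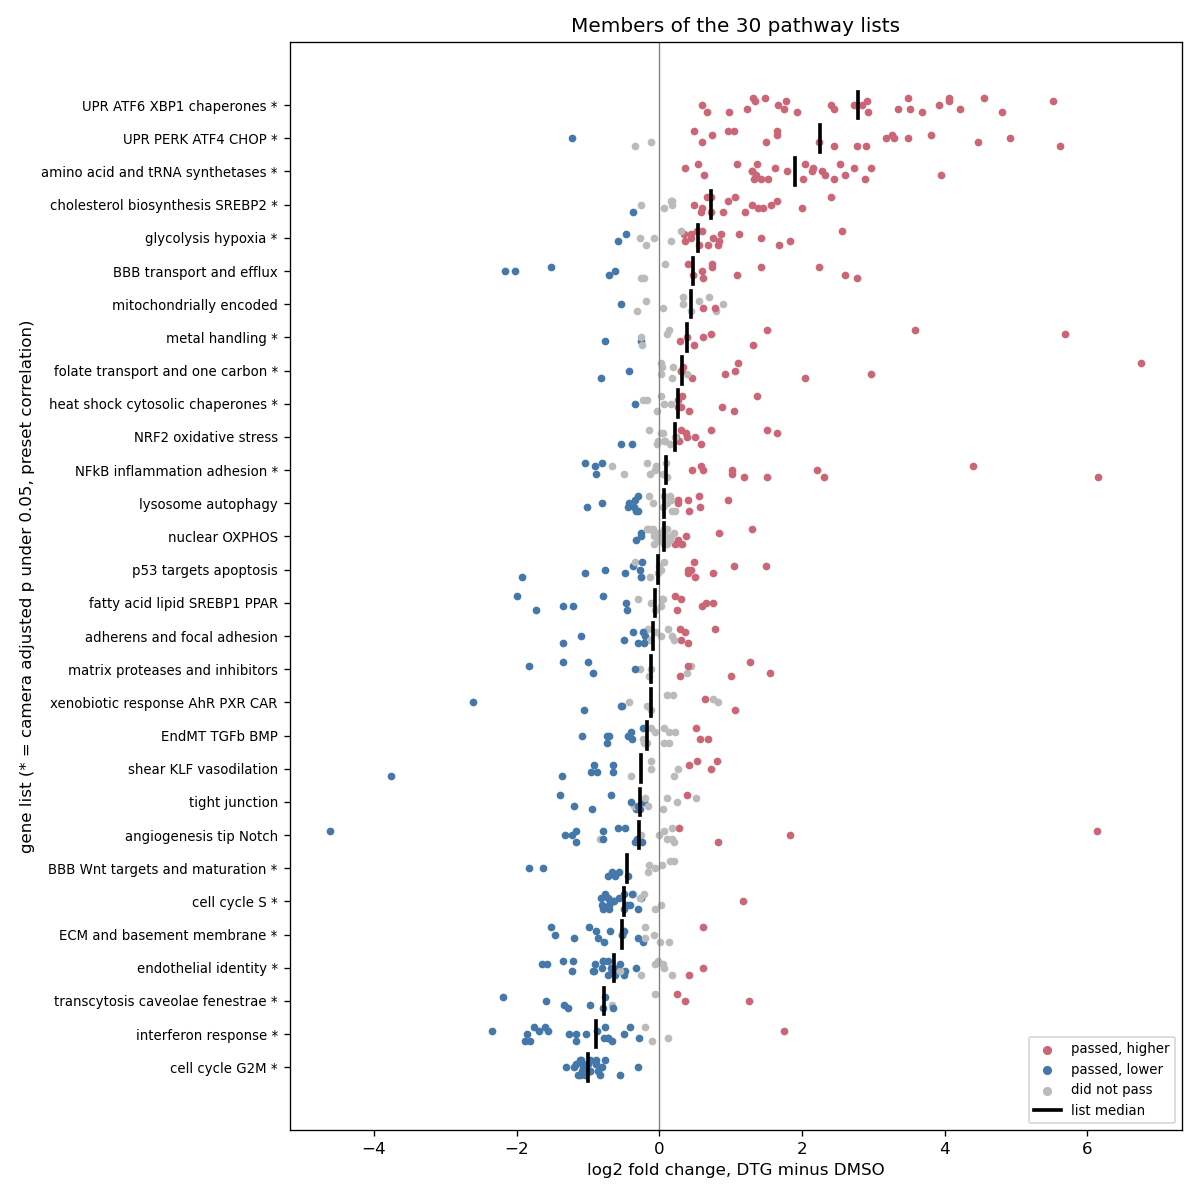
Log2 fold change (DTG minus DMSO, horizontal axis) of each measured member of the 30 pathway lists, red for genes that passed as higher, blue for genes that passed as lower and grey for the rest, with list medians in black. Medians run from -1 for mitotic genes to 2.78 for ATF6 and XBP1 chaperones.

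Markers of other cell types were low for the most part. All 14 mural cell markers, 9 of 11 fibroblast markers, 11 of 14 microglia and macrophage markers and 6 of 6 erythroid markers had a mean under 1 CPM, as did 7 of 9 astrocyte, 7 of 10 neuron, 8 of 10 oligodendrocyte, 4 of 6 lymphatic and 8 of 9 epithelial and choroid markers. Among the exceptions, the gap junction gene Gja1 rose from 60.03 ± 4.60 to 230.3 ± 24.1 CPM, Lyve1 rose from 194 ± 8.13 to 347 ± 41.9 CPM, and Tmem119 fell from 26.7 ± 2.98 to 6.93 ± 0.77 CPM. Aqp1 was at 1467 ± 349 CPM in DMSO and 1513 ± 169 in DTG. Of 4 tested mural markers 1 rose and 1 fell, of 3 fibroblast markers 2 rose, of 3 microglial markers 1 rose and 2 fell, and of 3 neuron markers 1 rose, and none of these 4 lists passed camera (adjusted p = 0.607, 0.351, 0.140 and 0.351). The astrocyte, oligodendrocyte, lymphatic and epithelial lists had 2 tested genes each and the erythroid list 0, so no list test was run on these.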

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

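The alternatives here were set before the data were examined. The counts of 3860 higher and 4130 lower genes stayed within 1.5 times in all alternatives except 2: 2536 genes were higher with library size alone, where the median of all genes shifted by -0.17 log2, and a fold threshold of 1 log2 left 885 higher, 1177 lower and 2062 in all by construction. Leaving out a library in turn gave 6470 to 8518 calls, and DESeq2 and limma-voom gave 7780 and 7988. Alternatives other than the stricter and the fold threshold, which only take part of the calls, shared between 79.9% and 99.9% of those of the 7990 calls it tested, with the same sign, and 0 calls in them had the opposite sign. At adjusted p under 0.01, 5900 genes passed. The title numbers did not pair the libraries (correlations of same-numbered deviations -0.282, 0.009 and -0.052, and no library correlated best with its own number). DMSO and DTG libraries of the same P tag correlated at 0.105 to 0.196, and those of different tags at -0.282 to 0.009. With the numbers as a replicate block 3543 genes were higher and 3728 lower, 7271 in all, and 16 lists passed. With the P tag as a term 8011 genes passed. Of 30 lists 16 passed camera, 0 with an estimated correlation and 25 by fry, which tests another question. With an estimated correlation the chaperone list had adjusted p = 0.136 and the PERK, ATF4 and CHOP list 0.196. The tight junction list passed fry alone (adjusted p = 0.000284). The estimated correlations of 0.56 and 0.514 widen the test for the first 2 of these by construction. Lists with negative estimates lost their call as well: caveolae and vesicular transport (-0.012), metal handling (-0.043) and heat shock (-0.004). Correlation between genes therefore does not account for every lost call. Several lists share an adjusted p of 0.196 in camera with an estimated correlation because the adjustment gave them a common value. Their unadjusted p in that test ran from 0.0303 (folate and one-carbon) to 0.0784 (NF-kB). The shared value therefore does not rank these lists. For named genes over their alternatives, 1283 results kept their side of the threshold, 12 lost a call, 3 gained one and none reversed. A planned change of pseudocount was not run, since the values are counts. In simulation 46.6% of changes of 0.5 log2 were found over all count levels, and how this depends on depth was not tested. Each simulated run changed 200 genes, where 7990 passed in the data, so this share need not hold here.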

Other observations

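The gene lists of the first paragraphs and the tests on cell share, transcription factors, myeloid transcripts, tags and single libraries were chosen after the result was seen, and those on chance splits, length and GC content, and read-through before it. The 9 lists form a family of their own. The secretory route behind the chaperones rose almost as a whole. Of 27 genes of the ER translocon, signal peptidase and oligosaccharyltransferase 26 rose (26 adjusted over the list alone, median 1.10 log2, camera adjusted p = 1.37e-24, and adjusted p = 0.0572 with an estimated correlation), with Ssr3 rising from 295 to 1077 CPM and Sec61a1 from 229 to 634 CPM. Of 29 COPII and COPI transport genes 28 rose (28 adjusted over the list alone, median 0.87 log2, camera adjusted p = 3.00e-19, and adjusted p = 0.188 with an estimated correlation), led by Kdelr3 (3.30 ± 0.20 log2), Sec24d (2.59 ± 0.14) and Mcfd2 (2.33 ± 0.10). Of 24 constitutive proteasome subunit genes 24 rose with TMM and 20 with library-size scaling (24 adjusted over the list alone with TMM), with a median of 0.48 log2 with TMM and 0.31 with library-size scaling (camera adjusted p = 3.41e-06, and adjusted p = 0.294 with an estimated correlation). The proteasome subunit genes Psmb8, Psmb9 and Psmb10, held in the antigen presentation list below instead, passed as lower (-0.94, -1.33 and -0.44 log2). Of 27 ribosomal protein genes 21 rose with TMM and 5 with library-size scaling (23 adjusted over the list alone with TMM, camera adjusted p = 0.00441, and adjusted p = 0.600 with an estimated correlation).

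Antigen presentation genes fell beside the interferon genes. Of 14 genes of the MHC class I pathway 12 fell (13 adjusted over the list alone, median -0.85 log2, camera adjusted p = 7.59e-06, and adjusted p = 0.236 with an estimated correlation), with B2m falling from 366 to 181 CPM and the peptide-loading gene Tapbp from 292 to 113 CPM. Reported substrates of IRE1-dependent mRNA decay fell in 6 of 8 cases and rose in 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.00557, and adjusted p = 0.294 with an estimated correlation), among them Bloc1s1, by 0.97 ± 0.13 log2, and Tapbp, which both lists hold. Receptor genes of ER-phagy fell in 5 of 7 cases (5 adjusted over the list alone, camera adjusted p = 0.0403, and adjusted p = 0.2999 with an estimated correlation), with Ccpg1 falling by 1.05 ± 0.10 log2. This call was lost without DTG replicate 1 or 2 (adjusted p = 0.0506 and 0.0591, range over the 6 fits 0.0235 to 0.0591). Of 12 genes typical of sinusoidal and scavenger endothelium 7 were high enough to test, of which 4 fell and Lyve1 rose (4 and 1 adjusted over the list alone, camera adjusted p = 0.000291, and adjusted p = 0.080 with an estimated correlation). Of those that fell, Stab1 and Stab2 are also members of the caveolae and vesicular transport list and Cd36 of the fatty acid list. The result is therefore not independent of those lists. Levels in DMSO ran from 1664 CPM for Stab1 and 394 for Stab2 to 3.63 for Gata4 and 1.29 for Oit3, and Clec4g, Cd209a, Fcgr2b, Dnase1l3 and Mrc1 stayed under 0.1 CPM. Of 16 genes enriched in brain endothelium, some of them also used by other cells, 8 were high enough to test, of which Slc7a5 and Slc2a1, also members of other lists here, rose and 3 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.821), and Mfsd2a, Slco1a4, Slco1c1, Slc22a8 and Lef1 stayed at or below 0.119 CPM in both groups.

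The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 7990 genes, 1 of the 10 splits gave as many, and the highest of the others gave 0. A treatment by P tag interaction, with 2 residual degrees of freedom, called 0 genes with edgeR's quasi-likelihood test (1351 at an unadjusted p under 0.05), and no other tool was run on it. The P tag, given treatment, called 136 genes. Removing the trend over transcript length and GC content moved the median by over 1.5 times in 2 of the 16 lists that passed camera, from -0.45 to -0.19 log2 for the Wnt and maturation genes and from 0.10 to 0.19 for the NF-kB genes.

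The fall of endothelial identity genes was weighed against technical explanations. A share of the counts taken up by rising ER transcripts would lower all other genes of a library alike. The list lay at -0.63 log2 from the median of all genes with TMM, RLE, upper-quartile and library-size scaling. Scaling moves every gene of a library alike, so it leaves this distance unchanged. The distance argues against such a share as the reason why the list lay below other genes. A lower share of endothelial cells would lower each endothelial gene alike, but Cdh5 lay 0.81 log2 above the list median. Cdh5 is 1 gene and was chosen after its value was seen, so a lower share as part of the pattern is not excluded. Transcript length and GC content explained 1.2% of the variance of fold changes, and the list median was -0.60 after their trend was removed (30 of 30 members had values). A candidate explanation, that only mRNAs translated at the ER were lost, was also tested. The 4 transcription factors Sox17, Sox18, Erg and Fli1, translated in the cytosol, passed as lower in 4 of 4 cases, so loss at the ER does not account for these 4. They were chosen after their values were seen, and 4130 of all 14101 genes tested were lower, so they do not decide the cause for the other members. Loss at the ER may add to the pattern, and lower transcription in response to DTG stays open as a hypothesis.

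Il6, Il12b, Il23a and Cxcl2 rose although Il12b and Il23a are better known from myeloid cells. Myeloid cells in the DTG cultures would bring their abundant transcripts, but the highest of 8 (Ptprc, Tyrobp, Csf1r, C1qa, C1qb, C1qc, Itgam and Aif1) reached 0.166 CPM in any DTG library, where Il12b was at 10.8 CPM or more. Of the wider macrophage list, Cd68 was at 91.4 CPM in DMSO and 140 in DTG, while the 2 other tested members, Tmem119 and Lyz2, fell. The 8 were chosen after the result was seen. Outside them S100a9 and Oscar, also known from myeloid cells, rose from 0.0991 to 7.82 CPM and from 0.177 to 4.14 CPM. A difference between P4 and P5 libraries does not account for the rise of Il6, Il12b, Il23a and Cxcl2, since within tags the smallest difference of the 4 genes was 3.77 log2 CPM. A response of the endothelial cells themselves is a hypothesis that these tests leave open.

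Among genes that passed the adjusted p threshold, 24 went from a mean under 0.2 CPM in DMSO to at least 2 CPM in DTG, and 2, Lao1 and Rarb, went the other way. Read-through from a rising upstream neighbour was tested. Of the 6 with a tested same-strand neighbour within 50 kb the neighbour had risen by at least 1 log2 in 0% (Tcf25, Tfpt and Rpl21 rose by less), against 20% of 95 other low genes (Fisher's exact test, one-sided p = 1). The test as planned needed at least 20 such genes, so by that rule it cannot decide. A count over all 24, tried only after that, found 0 with a tested neighbour within 50 kb that rose by at least 1 log2, and most of them had no tested neighbour that near. That count rests on the same 6 genes, so it adds no data to the planned test, which stays undecided. It shows only that none of the 24 had a tested neighbour within 50 kb that rose by at least 1 log2. Read-through from farther, overlapping or untested genes, or from neighbours that rose by less, stays open. Counts from 1 DTG library alone were looked at too: in 24 of 24 every DTG library lay above 5 times the highest DMSO library. The 24 had been selected on these libraries through the count filter and the test, which leave out most genes carried by 1 library. This result was therefore largely fixed beforehand and decides nothing. Among the 24 are Il12b, Csn3, Mamdc2, Otog, Cox6a2, Gsdma, S100a9, Tenm4 and the Notch effector gene Hey2, and whether these reflect induced transcription or longer-lived mRNA was not tested.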
